A study of Mus musculus with 25 samples.

How the data were processed

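RNA of the mouse hypothalamus was measured on in-house printed, 2-colour oligonucleotide arrays, on which each array held tumor-bearing RNA in one dye and PBS control RNA in the other. Per the labels' protocols, male mice aged 8 weeks had received 1000000 CT-26.WT cells in 300 µl PBS, or PBS alone, under the skin, and were killed after 18, 72 or 192 h. The labels name 25 arrays of 13 biological replicates, with 5 replicates at 18 h, 4 at 72 h and 4 at 192 h. Replicates 1 and 2 of each time were polyA RNA and the others total RNA. Every total RNA replicate was hybridised in both dye orientations, and every polyA replicate in one orientation. The labels do not say whether a replicate was 1 mouse or a pool, so p-values measure the spread between these samples, which may be partly technical.

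Each array came with 3 scanner files of 10080 spots in 48 print blocks. Per the file headers, their values were spot intensities in 2 channels with the local background already subtracted, together with that background. The quantification software, the scanner settings and what separated the 3 files of an array are not given in the sources used here. The 3 files of an array correlated at r of 0.589 to 0.939 in log2 ratio across spots and were read as scans of one slide. Of 1512000 deposited intensities, 35.8% were 0 and 1194 were below 0, and a spot was used in a scan only where both channels were above 0. Between 3056 and 9839 spots per array were measured in this sense, and the median signal over background per array lay between 0.778 and 3.94. The number of arrays limits the precision.

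A table of the authors' own values per spot was also given for each array. The authors' values were log ratios, read here as natural log. Their scale is not stated in the sources used here. On bright spots their spread was 0.742 of that of the log2 ratios after block-wise loess (median over 25 arrays), where a natural log would give 0.693. Their medians per array lay between -0.0086 and 0.0077, so each array had been centred, and their sign matched that of the scanner ratios, turned to tumor over PBS, on 25 of 25 arrays (r across spots from 0.586 to 0.897). Their log base and normalization stay unknown, and they were used only as an alternative.

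Per scan, the log2 ratio of channel B over channel A was normalized by an intensity-dependent loess curve (limma loessFit, span 0.3, 4 iterations), with no further scaling between arrays. The mean of the 3 scans was the array's value, and the arrays of a replicate were averaged. Channel A was read as Cy3 and channel B as Cy5 from the order of the channels in the labels, and each array was turned to tumor over PBS by the dyes the labels give. Spots were named through the platform annotation given for this work. Of the 10080 spots, 9074 or 9066 by platform had 1 gene symbol, 12 had several and were not named, and 994 or 1002 had none. Their accessions were matched to RefSeq names of assembly GRCm38.p6 for 8985 or 8977 spots. No coordinates were used. Where several probes named a gene, the probe with the highest mean intensity stood for it, which left 8726 genes. The filter on dim probes, a value above background in at least 1 channel on at least 0.5 of the arrays, removed no gene of these.

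Several choices were made after the files were seen, before any test between tumor and PBS. To begin with, 6 of the 25 arrays were left out, namely the 5 arrays of 72 h replicates 1 and 2 and 1 of the 2 arrays of 192 h replicate 1. By probe name, their spot brightness did not follow that of the other arrays (median Spearman rho 0.0228 over 114 pairs, against 0.356 between platforms among the other arrays). No mirror image or rotation of the print layout brought them into register. This left 19 arrays of 11 replicates, with 5 at 18 h, 2 at 72 h and 4 at 192 h, and no polyA replicate at 72 h. Also, the deposited background-corrected intensities were used as given in place of a normexp correction, so the subtraction foreseen as an alternative was itself the setting used. Further, a total RNA replicate needed a value in both dye orientations. Finally, a gene was tested with values in at least 3 replicates at 18 h, 2 at 72 h and 3 at 192 h, in place of the stricter minimum fixed earlier for 13 replicates. This minimum was set after the numbers of genes were seen.

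Tests used limma 3.58.1 and data.table, version 1.17.8, in R 4.3.3. One lmFit and eBayes model over the 11 replicates held a coefficient per time and a dye term, the mean orientation of the replicate's arrays, which is 0 where both orientations were present. Where a gene had a lone polyA value, the dye term took it up, though n counts it. A difference between polyA replicates of opposite orientation was taken up as far as it was alike at 18 h and 192 h. It was taken up in full where a gene had polyA values at 18 h alone or at 192 h alone. What the dye term took up enters neither the SE nor the p-value. Each time, the average of the times, the 3 differences between times and a moderated F-test of any difference were tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 29 gene lists were fixed before the data were examined and tested where at least 5 members had values, with cameraPR (limma) at a preset correlation between genes of 0.01. It ran on the moderated statistics turned to z, because missing values did not allow camera itself, and fry was not run for the same reason. Adjusted p-values for lists were over the lists tested in a comparison. The test was repeated with the correlation estimated from the residuals. Exact sign-flip tests of list means per replicate were added as a description. The polyA arrays used were all on 1 print platform and the total RNA arrays on 2 others, so a difference between RNA types cannot be told apart from one between these platforms.

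The rule for named genes was fixed before the data were examined. It took, for each time and the average, up to 12 genes of each direction that passed with the same sign in the replicates, and the 10 symbols with the smallest p where fewer than 10 passed. For the differences between times it took genes only where they passed. It further took up to 4 members of each list and the hypothalamic neuropeptides. Since no gene passed, the 10 with the smallest p are given as values that did not pass, and the 4 members of each list are those with the smallest p over the 3 times and their average, each given in the comparison where that p occurred. Beyond the rule, the members at the ends of each list that passed the test are named, chosen after their values were seen. Pomc, Agrp, Npy and Crh were not analysed here.

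The model was tested on simulated data with 200 changed genes per comparison. A log2 change of 1 was found in 99% of changed genes at 18 h, 92% at 72 h, 99% at 192 h and 100% for the average. A log2 change of 0.5 was found in 23%, 1%, 33% and 95% of them. At a size of 1, the simulation gave a p under 0.05 for 5.25% of unchanged genes at 72 h and 5.11% on average, where the data gave 1.71% and 1.81% of all genes, so the simulated data did not behave like the real data there and these shares may not hold. For the difference between 192 h and 18 h the shares were 83% at a size of 1 and 0% at 0.5.

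The alternatives fixed before the data were examined were no background correction, print-tip loess, median centring alone, scaling between arrays, each scan file alone, no filter or a strict filter on dim probes, no dye term, an array-level fit with the replicate as a random block, RNA type as a covariate, each RNA type alone, the print platform as a random block, each time fitted alone, array quality weights, every probe tested, the authors' values, an adjusted p of 0.1, each replicate left out, the replicate number as a block and the estimated correlation. Those added after seeing the data were normexp with an offset of 50 after adding the background back, all 25 arrays joined by probe name, a value in 1 orientation as sufficient, and 2 replicates at each time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.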

Results

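The hypothalamus of BALB/c mice carrying CT-26.WT cells, a colon carcinoma line of the same mouse strain grown under the skin, was compared with that of PBS-injected mice at 18, 72 and 192 h after injection. Each array measured the ratio of tumor-bearing to PBS hypothalamus directly. Values from 19 arrays entered the comparisons, which form 5 biological replicates at 18 h, 2 at 72 h and 4 at 192 h. Each replicate gave a value for 2556 to 7777 genes. The widest spread was that of 18 h replicate 2, a single polyA array with 3306 of 10080 spots measured, whose log2 ratios had an SD over genes of 0.90. The SD of the other replicates lay between 0.21 and 0.56. All values are log2 ratios of tumor over PBS. Their direction is likely rather than settled, since the files call the channels only A and B. It rests on the order of the dyes in the labels. The sign of the authors' values matched on 25 of 25 arrays. This match bears on the direction only if the authors' values are themselves tumor over PBS.

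The dye of a sample left a mark on the ratios of many genes. In the 7 pairs of arrays that measured one replicate in opposite dye orientations, the log2 ratios, turned the same way, correlated across genes with a median r of -0.26, and 6 of the 7 were below 0. Between different replicates the median was 0.18 in the same orientation (80 pairs) and -0.18 in opposite ones (83 pairs). The dye term of the limma model was past an adjusted p of 0.05 for 252 of 5581 genes. It rests on polyA replicates 1 and 2 of 18 h and 192 h alone. Replicate 1 had tumor in Cy5 and replicate 2 in Cy3 at both times, so dye and replicate number coincide in it. The 7 replicates with both orientations, in which such a bias cancels, correlated with each other at a median r of 0.0215 over 21 pairs. Genes are not independent replicates, and these correlations describe the arrays only.

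**Figure D1:**
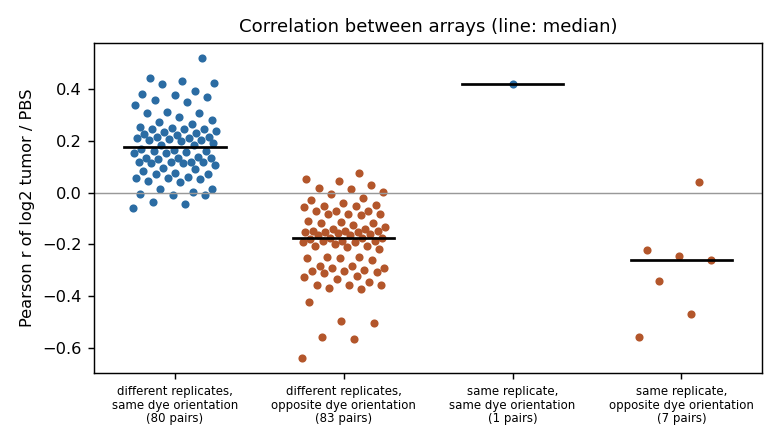
Pearson correlation across genes of the log2 ratio of tumor over PBS (vertical axis, no unit) for each pair of arrays used, grouped by replicate and dye orientation (horizontal axis), with a line at each median. Pairs in opposite orientations lie mostly below 0, with medians of -0.18 between replicates and -0.26 within them.

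The comparison at 18 h asked what differed in the hypothalamus within the first day of tumor cells being present. The smallest p-values belonged to Cbll1, an E3 ubiquitin ligase, with a log2 ratio of 0.47 ± 0.09 (SE, n = 5), and to Robo4, an endothelial guidance receptor, at 0.46 ± 0.10 (SE, n = 5). Both were above 0 in 5 of 5 replicates. Rcan3, a regulator of calcineurin, was at -0.53 ± 0.12 (SE, n = 4), and Dynlrb2, a dynein light chain of ciliated cells, at -0.53 ± 0.12 (SE, n = 3), each with the same sign in every replicate measured. Oxct2a was at 0.55 ± 0.13 (SE, n = 3) and Nanog at 0.66 ± 0.13 (SE, n = 3), with replicate values of Nanog from -0.08 to 1.45. Among the other genes with the smallest p, Trim34a (1.07), Bspry (0.51), Cntn3 (1.26) and Ubfd1 (-0.70) also varied widely between replicates, and the values of Cntn3 ran from -1.23 to 5.14. The extremes of Nanog and Cntn3 came from polyA replicates 1 and 2. The dye term took up that difference, fully for Nanog and largely for Cntn3, so the SEs of both understate the spread. None of the 5066 genes tested passed the threshold in limma, and the smallest adjusted p was 0.887, which all of these genes shared. At an unadjusted p under 0.05 there were 271 genes, 137 above and 134 below 0, where 253.3 would fall by chance. Leaving out 18 h replicate 2 moved 27 of the 75 gene values named for 18 h that could still be given by over 1.5 times, and 7 of them changed sign, while each of the other 18 h replicates moved 9 to 15. With the 2 polyA replicates alone, 32 genes passed at 18 h, in a fit with a single residual degree of freedom. The total RNA replicates alone gave 0.

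Of the 27 gene lists tested at 18 h, none passed, and the smallest adjusted p was 0.498. The lowest unadjusted value belonged to the neuropeptide processing list, whose enzymes and granins mature peptide hormones, with 1 of 6 members above 0 and a mean of -0.22. Its members Cpe, a carboxypeptidase (-0.44 ± 0.16, SE, n = 4), Scg3 (-0.61 ± 0.28, SE, n = 4) and Pcsk1n (-0.22 ± 0.10, SE, n = 4) were below 0, and Cpd was at 0.26 ± 0.10 (SE, n = 5). Much of this came from 18 h replicate 2, where the list mean against all genes was -0.82, Scg3 was at -2.24 and Cpe at -1.39. The list mean was 0.08, -0.20 and -0.17 in the other replicates with at least 5 members measured. Replicate 3 had too few, with Cpe at 0.18, Cpd at 0.26 and no value for Scg3 and Pcsk1n. Without replicate 2 the neuropeptide processing mean at 18 h was -0.10. In the stress-related lists, 4 of 9 glucocorticoid-responsive genes and 8 of 11 immediate early genes were above 0, with means of 0.07 and 0.10. Hsd11b1, which regenerates active glucocorticoid, was at 0.50 ± 0.15 (SE, n = 4), Cdkn1a at 0.25 ± 0.13 (SE, n = 3) and Mt1, a metallothionein, at 0.14 ± 0.09 (SE, n = 5). Fos was at 0.65 ± 0.22 (SE, n = 5), with values from -0.21 to 2.53, and Bdnf at -0.36 ± 0.16 (SE, n = 4).

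Inflammatory and immune lists at 18 h held small values. For cytokines and the NF-kB response, 9 of 15 members were above 0, with a mean of 0.02 and an adjusted p of 0.866 (limma cameraPR). Vcam1 was at 0.18 ± 0.12 (SE, n = 4) and Tgfb1 at 0.18 ± 0.14 (SE, n = 3). Il6ra on average over the times was at -0.11 ± 0.08 (SE, n = 9), and Ccl4 at 192 h at -0.14 ± 0.15 (SE, n = 4). Acute phase and complement genes had 6 of 8 members above 0 and a mean of 0.07. Their members C1qc and C1ra were at 0.32 ± 0.20 (SE, n = 4) and 0.20 ± 0.14 (SE, n = 3), C1qa was at -0.18 ± 0.16 (SE, n = 4), and Agt, which encodes angiotensinogen, was at -0.18 ± 0.14 (SE, n = 2) at 72 h. For interferon response and antigen presentation, 5 of 7 were above 0 with a mean of 0.15. Oasl2 was at 0.60 ± 0.16 (SE, n = 3), Ifit3 at 0.39 ± 0.19 (SE, n = 3), Usp18 at 0.20 ± 0.15 (SE, n = 3) and Irf8 at -0.15 ± 0.13 (SE, n = 3). In polyA replicate 1, Oasl2 was at -0.004 and Ifit3 at -0.06, lone polyA values that the dye term took up. Their estimates thus rest on total RNA replicates 4 and 5, with Oasl2 at 0.58 and 0.61 and Ifit3 at 0.68 and 0.11. Adjusted p was 0.498 for the acute phase and the interferon lists.

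Markers of other cell types, which could show a shift in the dissected tissue, did not pass in any list at 18 h. The mean log2 ratio was 0.00 for microglia and macrophages (8 of 12 above 0), -0.02 for astrocytes (4 of 9), 0.01 for oligodendrocytes and myelin (5 of 8), -0.05 for pan-neuronal markers (10 of 22), 0.01 for endothelial and mural cells (4 of 6), -0.10 for choroid plexus, ependyma and tanycytes (3 of 7) and -0.01 for neighbouring brain regions (6 of 9). Cd53 was at -0.37 ± 0.17 (SE, n = 3) and Slc1a3, the glial glutamate transporter, at -0.31 ± 0.13 (SE, n = 3). The Cd53 estimate rests on replicates 4 and 5 (-0.25 and -0.49), as the dye term took up its lone polyA value, 0.24 in replicate 2. S100b was at 0.19 ± 0.12 (SE, n = 4), Ntsr2 at 0.20 ± 0.13 (SE, n = 5) and Ndrg2 at -0.23 ± 0.16 (SE, n = 5). Among myelin genes, Tspan2 was at 0.25 ± 0.12 (SE, n = 5), Mag at -0.19 ± 0.12 (SE, n = 5) and Mal at -0.22 ± 0.14 (SE, n = 4). Camk2b (-1.15), Syp (-0.78), Map2 (-0.47) and Camk2a (1.35) varied between replicates, and Camk2a ran from -0.56 to 4.59. In the ependymal list, Kl was at -0.14 ± 0.14 (SE, n = 3) and Fabp7 at 0.07 ± 0.15 (SE, n = 4). Dynlrb2 was the single gene of any list and time that passed when adjusted over the list alone, against 0 list members adjusted over all genes. Anpep was at -0.14 ± 0.12 (SE, n = 4), Ocln at 0.13 ± 0.14 (SE, n = 4), Nrgn at -0.39 ± 0.17 (SE, n = 5) and Lef1 at 0.13 ± 0.11 (SE, n = 4).

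Neuronal signalling lists lay slightly below 0 at 18 h without passing. The mean was -0.09 for GABA and glutamate transmission (3 of 14 above 0), -0.04 for monoamine and acetylcholine systems (6 of 14), -0.09 for neuropeptide and feeding receptors (6 of 15) and -0.09 for hypothalamic transcription factors (2 of 9). Grin2b, an NMDA receptor subunit, was at -0.33 ± 0.15 (SE, n = 4) and Gad2, which makes GABA, at -0.24 ± 0.12 (SE, n = 4). Gabra3 was at -0.40 ± 0.18 (SE, n = 3), over values from -2.91 to 1.62. These extremes came from polyA replicates 1 and 2, whose difference the dye term took up. Hrh1, Slc18a3 and Chrm2 were at -0.18, -0.22 and -0.25. The tachykinin receptors Tacr3 and Tacr1 were at -0.27 and -0.54, and the cholecystokinin receptor Cckbr at -0.56 ± 0.22 (SE, n = 5). Tacr1 was at 0.17 without 18 h replicate 1 and also without replicate 2, as the dye term takes up a lone polyA value. Dlx1, Nkx2-1 and Fezf1 were at -0.30, -0.20 and -0.15. For the circadian clock, 7 of 10 members were above 0, with Per2 at 0.38 ± 0.18 (SE, n = 3), Nr1d2 at 0.29 ± 0.13 (SE, n = 3) and Clock at -0.94 ± 0.49 (SE, n = 4). The median of this list was 0.05 and its mean -0.01. The glucocorticoid list (median -0.03, mean 0.07) and the neighbouring region list (median 0.05, mean -0.01) also had medians and means of opposite sign.

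Lists of basic cell functions at 18 h did not pass. The mean was -0.02 for cytosolic ribosomal proteins (16 of 32 above 0), -0.01 for oxidative phosphorylation (20 of 41), -0.06 for the proteasome (5 of 17), -0.08 for heat shock and chaperones (5 of 17), -0.07 for the antioxidant response (6 of 15), -0.05 for cell cycle and proliferation (2 of 8), -0.04 for thyroid hormone and energy sensing (4 of 9) and -0.12 for cholesterol and sterol synthesis (1 of 7). Without 18 h replicate 4, the ribosomal and oxidative phosphorylation lists passed below 0 at 18 h, with means of -0.08 and -0.08 and an adjusted p of 0.019 for each. Irs2, an insulin signalling adaptor, was at -0.20 ± 0.09 (SE, n = 5) and below 0 in 5 of 5 replicates. Psmb3 and Psmd7 were at -0.48 ± 0.16 (SE, n = 5; -0.17 without 18 h replicate 2) and 0.29 ± 0.11 (SE, n = 4), and Psmd1 at -0.31. The chaperonin subunit Cct8 was at -0.39 ± 0.14 (SE, n = 4), Dnaja1 at -0.41, the thioredoxin reductase Txnrd1 at -0.33 ± 0.13 (SE, n = 4), Mt3 at -0.37 and Gclm at -0.19. Mcm5 (0.38), Top2a (-0.27), Bub1b (-0.21) and Birc5 (0.29) split by sign, and Msmo1 and Mvk were at -0.25 and -0.21. Ndufa7, Cox4i1, Rpl22 and Rpl34 were at -0.45, -0.25, -0.30 and -0.27.

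At 72 h, genes of the cytosolic ribosome and of oxidative phosphorylation rose together by small amounts in the preset-correlation test, but neither list passed with an estimated correlation (adjusted p = 0.352 for both). Of 23 ribosomal protein genes, 21 were above 0, with a median of 0.13 and a mean of 0.12, and the list passed at an adjusted p of 0.00332 (limma cameraPR). Its members ran from Rps19 (-0.15 ± 0.19, SE, n = 2) to Rps20 (0.29 ± 0.19, SE, n = 2), with Rpl10 at 0.24 and Rpl38 at 0.21. Of 27 oxidative phosphorylation genes, 22 were above 0, with a median of 0.10 (adjusted p = 0.0114), from Cox8a (-0.22 ± 0.17, SE, n = 2) to Ndufa4 (0.34 ± 0.23, SE, n = 2) and Ndufa3 (0.33 ± 0.16, SE, n = 2). Both means were above 0 in 2 of 2 replicates. No member of either list passed on its own, over all genes or adjusted over the list alone. Print-tip loess lowered both means to 0.06 and ended both calls (adjusted p = 0.129 for each). Leaving out a 72 h replicate leaves a lone one, assumed to vary like those of the other times, so a call lost there says little about the effect. Without replicate 4 the ribosomal mean was 0.09 and the oxidative phosphorylation mean 0.10 (0.259 for each), and without replicate 3 they were 0.14 (0.0205) and 0.09 (0.113). With RNA type as a covariate the means were 0.15 and 0.09 (adjusted p = 0.000143 and 0.0445). All 72 h values are of total RNA, so the covariate only carries over an RNA difference from the other times. It is no test of the 72 h calls.

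The other 10 lists at 72 h did not pass, with means between -0.06 and 0.15 and adjusted p of 0.350 or more. Cell cycle genes were above 0 in 5 of 5 members (mean 0.13), chaperones in 4 of 5 (0.10), the antioxidant response in 4 of 6 (0.15) with Txn2 at 0.69 ± 0.37 (SE, n = 2; -0.33 and 1.71 in the replicates), oligodendrocyte genes in 4 of 5 (0.06) and neighbouring region markers in 4 of 5 (0.12), with Neurod2 at 0.44 (0.88 and 0.00 in the replicates) and Drd2 at 0.20 (0.32 and 0.08). Pan-neuronal markers were above 0 in 3 of 8, astrocyte markers in 2 of 5, receptors in 2 of 7 and neuropeptides in 5 of 10, with Nucb2, the precursor of nesfatin, at -0.50 ± 0.20 (SE, n = 2; -0.03 and -0.96 in the replicates). The antioxidant list mean against all genes was -0.04 in 72 h replicate 3 and 0.36 in replicate 4, and the list passed without replicate 3 (0.36, adjusted p = 0.0212), where a lone replicate is left. Immediate early genes had a median of 0.03 and a mean of -0.06. Gad1 was at -0.46 ± 0.22 (SE, n = 2; -0.82 and -0.10 in the replicates). Of the pituitary markers, which had too few members for the test, Lhb was at 0.28 at 72 h, and Pitx1 and Tbx19 were at 0.27 and 0.18 at 18 h. Of the blood cell markers, also too few, Cd79a was at -0.59 at 72 h (-1.09 and -0.10 in the replicates), and Cd79b and Bpgm were at 0.39 and -0.45 at 192 h.

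Single genes at 72 h did not pass in limma, with 0 of 1934 tested and a smallest adjusted p of 0.992. The smallest p-values belonged to Tagap1 (-0.79 ± 0.20, SE, n = 2), the MAP kinase phosphatase Dusp1 (-0.43 ± 0.14, SE, n = 2), the transcription factor Foxo4 (-0.59 ± 0.17, SE, n = 2), the potassium channel subunit Kcne1 (-0.61) and the zinc transporter Slc39a13 (-0.54). Ywhag, a 14-3-3 protein, was at -0.56, Smg9 at -0.46, Sting1, the adaptor of cytosolic DNA sensing, at -0.43, Fnbp4 at -0.50 and Ccdc150 at 0.77. Each had the same sign in both replicates, but often at very different sizes. Leaving out either 72 h replicate moved 14 of the 19 gene values named for 72 h by over 1.5 times, and 2 changed sign. Without replicate 3, Kcne1 was at -0.15, Slc39a13 at -0.16, Ywhag at -0.23, Sting1 at -0.17 and Ccdc150 at 0.11. At an unadjusted p under 0.05 there were 33 genes, 10 above and 23 below 0, against 96.7 by chance. With so few, the p-values at 72 h may be too large, and the absence of genes there says little. Without 72 h replicate 4, 1 gene passed, Zfp385a at 2.09, which rests on a lone replicate assumed to vary like those of the other times.

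At 192 h, ribosomal protein genes rose in the preset-correlation test, while under median centring alone, which moved the median of all genes to -0.14, their mean was -0.12. With an estimated correlation the list did not pass (adjusted p = 0.752). Of 32 members, 29 were above 0, with a median of 0.09 and a mean of 0.09 (limma cameraPR adjusted p = 0.000273). The highest were Rps25 (0.26 ± 0.13, SE, n = 4), Rpl7a (0.20 ± 0.13, SE, n = 3) and Rpl9 (0.19 ± 0.14, SE, n = 4), and the lowest Rps13 (-0.08 ± 0.17, SE, n = 3). The highest values rested on polyA replicates: Rps25 was above 0 in 2 of 4 replicates and stood at 0.10 without replicate 1 and 0.13 without replicate 2, and Rpl7a was above 0 in 1 of 3, at 0.66 in replicate 2. No member passed over all genes or adjusted over the list alone. Set against the mean of all genes, the list's mean was above 0 in 3 of 4 replicates. In polyA replicates alone it was 0.17 (adjusted p = 0.000892) and in total RNA replicates alone 0.04 (0.441), and 0.08 (0.00166) with RNA type as a covariate. The call was lost without 192 h replicate 1 (mean 0.06, adjusted p = 0.195) or replicate 2 (0.06, 0.197), without background correction (0.04, 0.477) and under median centring alone (-0.12, 0.809).

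The other 18 lists at 192 h did not pass, and the next smallest adjusted p was 0.166, for the proteasome. Of its 14 members 10 were above 0 (mean 0.09), with Psmc4 at 0.45 ± 0.17 (SE, n = 3). Chaperones were above 0 in 11 of 15 (0.06), with Hsp90b1 at 0.31 ± 0.13 (SE, n = 3), neuropeptides in 8 of 16 (0.03), thyroid hormone and energy sensing genes in 1 of 6 (-0.10) and sterol synthesis genes in 3 of 6 (-0.07). In these last lists Srebf1, which drives lipid synthesis genes, was at -0.38 ± 0.13 (SE, n = 3), Fdft1 at -0.14, Ptpn1 at -0.23, Fasn at -0.24 and Stk11 at -0.13. Myelin genes were above 0 in 1 of 8 (mean -0.08), with Nkx2-2 at 0.22 ± 0.09 (SE, n = 4), astrocyte markers in 3 of 9 (-0.06) and pan-neuronal markers in 3 of 15 (-0.09). Foxb1 was at 0.16, Fosb at 0.22, Tef at 0.16, Rgs5 at -0.15, Eng at -0.18 and Col25a1 at -0.13. The sign of the test differed from that of the list's median or mean, all of them between -0.03 and 0.02, for cytokines, ependymal markers, the clock, oxidative phosphorylation and the antioxidant response.

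Single genes at 192 h gave 0 of 2802 past the threshold in limma, with a smallest adjusted p of 0.372. It was shared by Dbf4, a regulatory subunit of the Cdc7 kinase (-1.49 ± 0.25, SE, n = 3), the brain kinase Brsk2 (1.23 ± 0.23, SE, n = 3) and the junctional adhesion molecule Jam2 (1.00 ± 0.17, SE, n = 3). Replicate values ran from -3.93 to 0.07 for Dbf4, whose lowest value came from a single polyA array. They ran from -3.52 to 6.72 for Brsk2 and from -4.68 to 6.87 for Jam2, with opposite signs in the polyA replicates of opposite dye orientation. None of these genes had a polyA value at 18 h, so the dye term took up the whole difference between the polyA replicates of 192 h. Their SEs and p-values leave that difference out and understate the spread. The arginine methyltransferase Prmt5 was at -0.88 ± 0.19 (SE, n = 3) and below 0 in 3 of 3 replicates. Scly was at 0.56 ± 0.13 (SE, n = 3), Tob2 at -0.36 ± 0.10 (SE, n = 4), Map3k12 at -0.50, the tetraspanin Cd151 at -0.52, Shc3 at -0.48 and Pagr1a at -0.55. At an unadjusted p under 0.05 there were 119 genes, 46 above and 73 below 0, against 140.1 by chance. Of the gene values named for 192 h that could still be given, leaving out replicate 2 moved 7 of 14 by over 1.5 times, with 2 changes of sign, and each of the other replicates moved 3 of 19 to 22, among them Shc3, at -0.22 without replicate 1. When 192 h was fitted alone 13 genes passed, Dbf4, Brsk2, Jam2, Prmt5 and Shc3 among them, but this fit of 4 replicates pooled the spread almost fully over genes (4010 degrees of freedom). Without 18 h replicate 2, Dbf4, Brsk2 and Jam2 passed, again with the difference between their polyA replicates taken up by the dye term. With total RNA replicates alone Prmt5 passed (-1.06, adjusted p = 0.0276).

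On average over the 3 times, ribosomal protein genes rose and pan-neuronal markers fell in the preset-correlation test, but neither passed with an estimated correlation (adjusted p = 0.103 for both). Of 21 ribosomal protein genes 19 were above 0, with a median of 0.08 (limma cameraPR adjusted p = 0.000182), led by Rpl35 (0.15 ± 0.07, SE, n = 10), Rpl26 (0.12 ± 0.09, SE, n = 10) and Rps29 (0.11 ± 0.06, SE, n = 11). Of 7 pan-neuronal markers none was above 0, with a median of -0.06 (adjusted p = 0.0211), from the synaptic vesicle protein Syp (-0.34 ± 0.17, SE, n = 9) and the microtubule protein Map2 (-0.22 ± 0.11, SE, n = 9) to Uchl1 (-0.01 ± 0.10, SE, n = 11). No member of either list passed over all genes or adjusted over the list alone. In total RNA replicates alone the ribosomal mean was 0.06 (adjusted p = 0.146) and the pan-neuronal mean 0.02 (0.967), and with RNA type as a covariate they were 0.07 (0.000264) and -0.14 (0.00583). PolyA replicates alone gave no average, since none was used at 72 h. An exact two-sided sign-flip test of the list means per replicate gave p = 0.227 for ribosomal proteins (above 0 in 7 of 11 replicates) and p = 0.321 for pan-neuronal markers (above 0 in 5 of 11), and 0.893 for both when adjusted over 28 lists. The pan-neuronal mean was -0.12 with all replicates. Its call was also lost without 18 h replicate 2 (mean -0.08, cameraPR adjusted p = 0.0657) or 4 (-0.08, 0.135), and without 192 h replicate 1 (-0.09, 0.1001) or 2 (-0.06, 0.428). Without 72 h replicate 3 or 4, which leaves a lone 72 h replicate, the mean was -0.07 or -0.09.

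**Figure D2:**
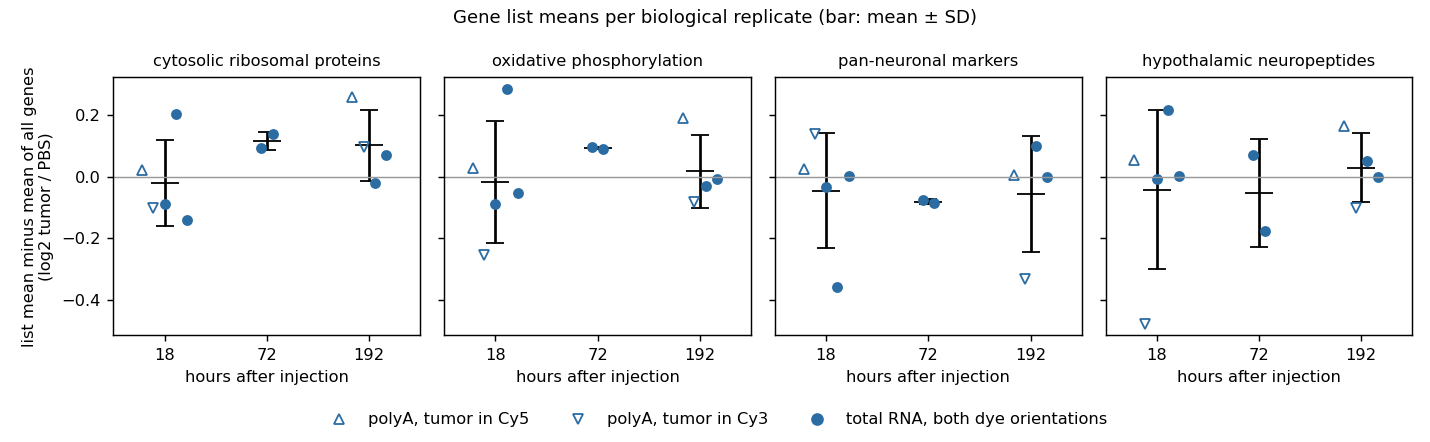
Mean log2 ratio of tumor over PBS of 4 gene lists, minus the mean of all genes (vertical axis, log2), by hours after injection (horizontal axis). Each symbol is a biological replicate, open triangles for polyA arrays of one dye orientation and filled circles for total RNA in both, and bars give mean ± SD. Ribosomal protein means lie above 0 in 2 of 2 replicates at 72 h and 3 of 4 at 192 h. Under median centring alone the 192 h list mean, with nothing subtracted, was -0.12, and the median of all genes was -0.14.

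The other 6 lists tested on average did not pass. Oxidative phosphorylation was nearest, with 18 of 26 members above 0, a mean of 0.04 and an adjusted p of 0.120, and Ndufa4 at 0.24 ± 0.11 (SE, n = 10). Hsp90aa1 was above 0 in 10 of 10 replicates, at 0.13 ± 0.07 (SE, n = 10), Sparc was at 0.21 ± 0.11 (SE, n = 11) and the serotonin receptor Htr2c at 0.09 ± 0.06 (SE, n = 10). The genes with the smallest p were Brsk2 (0.52), Adh5 (0.26 ± 0.09, SE, n = 9), pyruvate carboxylase, Pcx (-0.18 ± 0.07, SE, n = 11), the alarmin cytokine Il33 (0.20 ± 0.08, SE, n = 10), Etfa (0.19), Pik3r4 (0.20), Dync2h1 (0.19), Tmem167b (-0.18), Ywhag (-0.22) and Gpd2 (0.16). None of 1218 genes passed in limma, the smallest adjusted p was 0.996, and 22 had an unadjusted p under 0.05 against 60.9 by chance. As at 72 h, the p-values may be too large, and the absence of genes says little. Leaving out a replicate moved 1 to 5 of the 15 to 19 gene values named for the average by over 1.5 times, and Ywhag was at -0.11 without 72 h replicate 3.

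The differences between times asked whether the response changed as the tumor cells stayed longer. No gene passed in limma between 72 h and 18 h (1645 tested), 192 h and 72 h (1306 tested) or 192 h and 18 h (2507 tested), nor in the F-test over all times (1218 tested). At an unadjusted p under 0.05 there were 27, 37, 146 and 39 genes, against 82.25, 65.3, 125.35 and 60.9 by chance. Apart from 192 h against 18 h, these numbers fell short of chance, so the p-values may be too large there as well. Without 72 h replicate 4, 1 gene passed between 72 h and 18 h, Zfp385a again. The rule for named genes lists genes of these differences only where they pass, so none is listed.

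Some neuropeptide genes that control feeding and water balance were followed at the times where they had enough values. Pomc, Agrp, Npy and Crh were not analysed here, so main feeding peptides are missing. Of the genes below, only Cartpt, Avp and Oxt were tested at every time. The hypothalamic neuropeptide list had 9 of 18 members above 0 at 18 h, with a mean of -0.01, and its adjusted p was 0.918 (limma cameraPR). Pmch, which encodes melanin-concentrating hormone, was at -0.54 ± 0.19 (SE, n = 3) at 18 h, below 0 in 3 of 3 replicates, and at 0.31 ± 0.17 (SE, n = 4) at 192 h. Hcrt, the orexin precursor, was at -0.09 ± 0.14 (SE, n = 3) and 0.22 ± 0.11 (SE, n = 4) at these times, and above 0 in 4 of 4 replicates at 192 h. Cartpt was at 0.03 ± 0.18 (SE, n = 4), 0.02 ± 0.23 (SE, n = 2) and 0.08 ± 0.21 (SE, n = 3) at 18, 72 and 192 h. Avp, vasopressin, was at 0.13 ± 0.23 (SE, n = 3), -0.06 ± 0.26 (SE, n = 2) and -0.09 ± 0.18 (SE, n = 4), and Oxt, oxytocin, at 0.00 ± 0.12 (SE, n = 5), 0.04 ± 0.18 (SE, n = 2) and -0.16 ± 0.13 (SE, n = 4). Trh was at -0.18 ± 0.13 (SE, n = 3) at 18 h and galanin, Gal, at 0.30 ± 0.14 (SE, n = 3). Without 192 h replicate 2, the 192 h values were 0.08 for Pmch, 0.14 for Avp and 0.06 for Oxt. None of these passed, and the smallest adjusted p among them was 0.887.

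**Figure D3:**
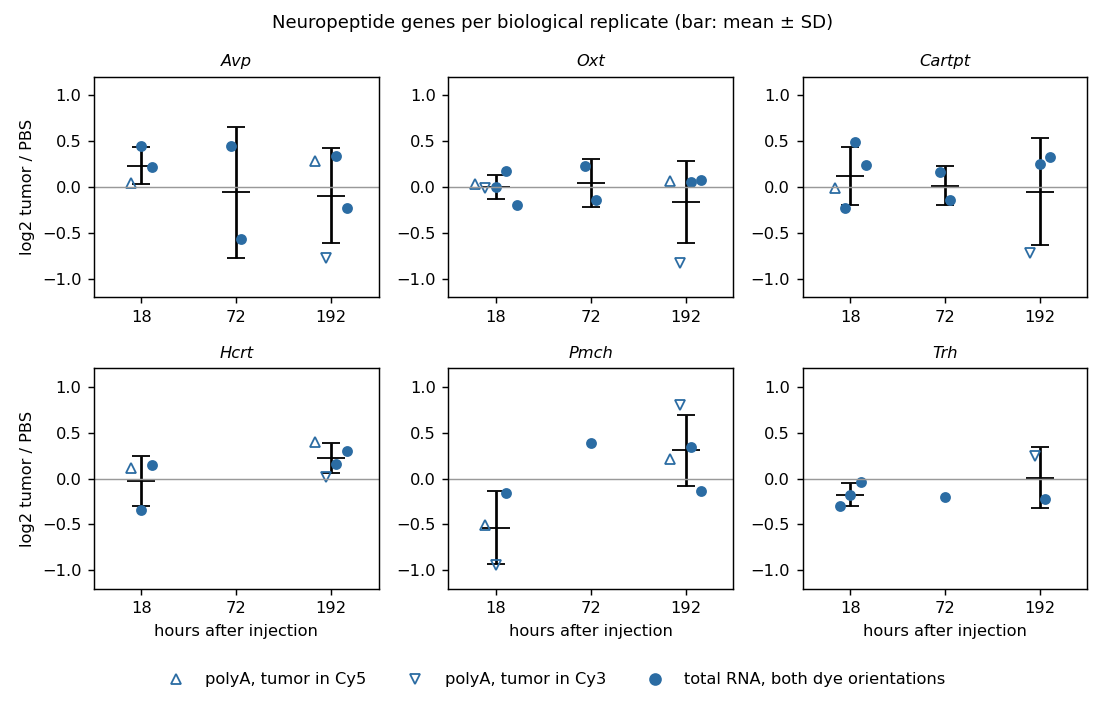
Log2 ratio of tumor over PBS (vertical axis) of 6 neuropeptide genes by hours after injection (horizontal axis). Symbols are biological replicates, open triangles for polyA arrays of one dye orientation and filled circles for total RNA in both, and bars give the plain mean ± SD where a time has more than 1 replicate. Where a time has more than 1 replicate, those of each gene lie on both sides of 0, apart from Pmch at 18 h, Trh at 18 h, Avp at 18 h and Hcrt at 192 h.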

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

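Of the tests below, those of spot brightness and dye bias for the ribosomal genes and the sign flips for gene lists were set before their results were seen, and the others after. In 134 groups of 4 or 5 replicates, 19 had a replicate far from the others. Chance alone gives about 1 in 20 where replicates vary alike. These did not, and many of the genes were picked for a small p, so the number cannot be set against that share. Of the 19, 11 were due to 18 h replicate 2, whose log2 ratios had an SD over genes of 0.90 and whose array quality weight was 0.206, and 3 to 192 h replicate 2. Without 18 h replicate 2, the values of Oxt, Tacr1, C1qc, Ndrg2, Clock, Dnaja1 and Mt3 at 18 h changed sign. For Tacr1 and C1qc this cannot be laid on replicate 2. Without replicate 1 they took the same values, as the dye term takes up the polyA value that is left.

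In 18 h replicate 2, Trim34a stood at 3.09 where the others lay between 0.36 and 0.43, and Hsd11b1 at 1.04 against 0.26 to 0.38. In the same replicate Pcx was at -0.548 (others -0.03 to 0.18), Cckbr at -2.26 (-0.44 to 0.01), Ndrg2 at -1.85 (0.05 to 0.52), Mag at -1.09 (-0.16 to 0.17), Clock at -4.14 (-0.22 to 0.40) and Dnaja1 at -2.43 (-0.09 to 0.18). Its list means also stood apart for receptors (-0.311, others -0.06 to 0.04), immediate early genes (0.978, others -0.19 to 0.09) and the proteasome (-0.576, others -0.10 to 0.05). In the other 18 h replicates, Ntsr2 was at 0.767 in replicate 4 (others -0.04 to 0.16), C1qa at -1.07 in replicate 1 (0.08 to 0.15), Tspan2 at -0.218 in replicate 3 (0.29 to 0.47) and Gclm at 0.0645 in replicate 5 (-0.34 to -0.27). At 192 h, replicate 2 stood apart for Oxt (-0.825, others 0.05 to 0.08), astrocyte markers (-0.364, others -0.01 to 0.06) and myelin genes (-0.344, others 0.03 to 0.10), and replicate 1 for Il6ra (0.294, others -0.04 to -0.02).

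Ribosomal protein genes lay above 0 at 72 h and 192 h. At 192 h the list's mean of 0.09 stood at percentile 100, as rounded, of 10000 random lists matched on intensity, whose mean was 0.004. The loess curve had already set ratios near 0 at every brightness, so the test cannot decide about an offset present before it. It shows only that, after this curve, other genes of like brightness did not share the shift. Under median centring alone, without the curve, the list mean was -0.12 and the median of all genes -0.14. The random lists also ignore the correlation between the list's genes, estimated at 0.17. Dye bias alike on all arrays is argued against as the whole cause, since it cancels in the 4 replicates of these times with both orientations. Their mean was 0.07 ± 0.07 (SD, n = 4), above 0 in 3 of 4, and the bound fixed beforehand, the mean less 2 standard errors, was 0.00535 and thus above 0. The margin is narrow, as the 95% interval of these 4 values reaches down to -0.03. In the 2 polyA replicates of 192 h, which were of opposite orientation, the list mean against all genes was 0.26 and 0.10. Noise shared by the genes of the list could account for the call, since with an estimated correlation the adjusted p at 192 h was 0.752. A change with time after injection remains a hypothesis, with a difference of 0.13 between the mean of the later times (n = 6) and 18 h (n = 5) and an exact two-sided permutation p of 0.0996 over 462 splits.

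Arrays of one replicate in opposite dye orientations gave opposed ratios. A response to the tumor cells shared by all times is argued against as the main content of single-array ratios, since replicates with both orientations correlated at a median r of only 0.0215. Most of these pairs join different times, so a response particular to one time would not show in this median. Gene-specific dye bias is the candidate explanation, as the ratio of channel B to channel A, whatever the labels, correlated between arrays of different replicates with a median r of 0.176 over 163 pairs. The dye term and the balanced orientations remove the part of it that is alike on all arrays.

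The 6 arrays left out had spot brightness that did not follow the other arrays by probe name. Their polyA RNA is argued against as the reason, since the polyA arrays used correlated with the total RNA arrays at a median rho of 0.346. Weak hybridization is argued against too, since the left-out arrays of one print platform correlated with each other at 0.4997. Probe names that do not belong to their spots may explain the pattern, as the left-out arrays of one print platform correlated with each other more than left-out arrays did with the rest, by 0.477 in median rho. Between the 2 left-out platforms the median rho was 0.405 over 5 pairs, which is the closer comparison. Between platforms of the arrays used it was 0.356, so these correlations cannot tell which set has the wrong names. For the arrays used, 32 of 33 ribosomal protein genes had enough values at 18 h, against 5066 of 8726 genes in all, which speaks for their names. The same was not counted for the left-out arrays. No biological explanation was tested, and 72 h has no polyA replicate without these arrays.

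For the difference between 192 h and 18 h, the real split of the 9 replicates gave 0 genes, so that all 100 of 100 splits necessarily gave as many and this count says nothing. The highest other split gave 9. At an unadjusted p under 0.05 the real split gave 146 genes, 33 of 100 splits gave as many, and the highest other gave 322, so chance is not excluded for that number. For gene lists on average over the times, 30 of 100 random sign flips of the 11 replicates gave as many lists as the real 2, and the highest other gave 3, so chance is not excluded there either.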

How the results depend on the processing

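The counts of genes on average, between 192 h and 72 h, between 192 h and 18 h and over all times were 0 in every alternative run, and most other counts of genes were 0 too. The exceptions were 32 genes at 18 h with polyA replicates only, 1 gene at 192 h with total RNA only, 13 at 192 h when each time was fitted alone, and 4 at 72 h with all 25 arrays joined by probe name, an alternative chosen after seeing the data. Leaving out one replicate at a time gave 0 to 1 genes at 72 h, 0 to 3 at 192 h, 0 to 1 between 72 h and 18 h, and 0 otherwise. The numbers of lists then ran from 0 to 2 at 18 h, 0 to 2 at 72 h, 0 to 1 at 192 h and 1 to 2 on average, against 0, 2, 1 and 2 with all replicates. Without 72 h replicate 3 the number at 72 h stayed at 2, but the antioxidant list passed and oxidative phosphorylation did not.

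At 18 h, 1 list passed with scan file 2 alone (GABA and glutamate transmission, below 0, adjusted p = 0.0483) and 1 with array weights (ribosomal proteins, below 0, 0.00134). At 72 h, 0 lists passed under print-tip loess, the authors' values, all 25 arrays, 1 orientation as sufficient and the estimated correlation, and 1 with file 1, file 2 or the strict filter, which left 236 genes. With the array-level fit, 3 of 29 lists tested passed at 72 h. At 192 h, 0 passed without background correction, under median centring, the strict filter, total RNA only, array weights and the estimated correlation, and 2 with file 3 (the proteasome, 0.0338, beside ribosomal proteins) and with polyA only (astrocyte markers, below 0, 0.00499). On average, 0 passed under print-tip loess, total RNA only, array weights, all 25 arrays and the estimated correlation, and 1 under median centring, file 2, file 3, the strict filter, the array-level fit, the authors' values, normexp and 1 orientation as sufficient. The normexp, all-array and 1-orientation settings were chosen after seeing the data. The means of 3 lists changed sign: pan-neuronal markers on average were at 0.02281 with total RNA only (adjusted p = 0.967), ribosomal proteins at 192 h at -0.12 under median centring (0.809), and oxidative phosphorylation at 72 h at -0.03 with all 25 arrays (0.901). Median centring moved the median of all genes at 192 h to -0.14, so the ribosomal mean did not fall below that median. The strict filter and single files test fewer genes; otherwise the cause was not tested.

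Ribosomal proteins passed in 27 of 32 alternatives at 72 h (adjusted p from 1.03e-05 to 0.901), 26 of 33 at 192 h (3.93e-05 to 0.809) and 27 of 31 on average (1.02e-05 to 0.536), oxidative phosphorylation at 72 h in 23 of 32 (0.00207 to 0.901) and pan-neuronal markers in 10 of 26 (0.00156 to 0.967). These counts leave out the estimated correlation, under which none passed. For 72 h they include settings that cannot move its ratios, such as leaving out an 18 h or 192 h replicate. Keeping total RNA only is another, with the ribosomal mean at 0.12 as before. The counts therefore overstate how stable the 72 h calls are. The filter on dim probes removed no gene, so running without it says nothing. Subtraction as an alternative to normexp was not run, being the setting used. The polyA replicates gave no 72 h or average values. With the replicate number as a block (replicates 1 to 4) the 4 tests of time differences gave 0 genes each. Of 8 pairs of replicates with the same number 3 correlated above 0.1, against 4 of 30 pairs with different numbers. The highest joined 18 h and 192 h polyA replicates of one dye orientation, at 0.55 for replicate 1 and 0.39 for replicate 2. After the dye term these were at -0.46 and -0.79, and polyA pairs of different numbers at 0.80 and 0.50. The dye term rests on these replicates alone, so its fit pushes residuals of equal numbers to opposite signs. Values after the dye term therefore say nothing about pairing. The numbers were not taken to pair samples, which these correlations do not settle. Precision is limited by the number of arrays and by dim spots, 35.8% of intensities being 0.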

Other observations

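Chaperone genes lay slightly above 0 in most replicates with both dye orientations. Their list mean was 0.04 ± 0.04 (SD, n = 7) and above 0 in 6 of 7 replicates, with an exact two-sided sign-flip p of 0.0469 that became 0.899 when adjusted over 28 lists. Over all 11 replicates the mean was -0.02 ± 0.19 (SD, n = 11). Markers of choroid plexus, ependyma and tanycytes were below the mean of all genes in 4 of 4 replicates at 18 h, with a mean of -0.15 ± 0.13 (SD, n = 4), and above it in 2 of 3 at 192 h, at 0.02 ± 0.02 (SD, n = 3). This difference between times was not tested.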
